A study of Rattus norvegicus with 24 samples.

How the data were processed

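RNA abundance was measured in lung and blood of 12 male Fischer rats on Illumina rat expression BeadChips, 1 array per rat and tissue. Per the labels, 6 rats breathed crystalline silica at 15 mg/m3 and 6 breathed filtered air, 6 hours per day for 5 days, and all were killed 32 weeks after the last exposure. The labels give an age of 3 months without saying at which point of the study. Source names give each rat a number, so the lung and the blood array of a rat could be paired. Blood RNA was depleted of globin transcripts, per the labels' protocols. The same blood extraction text stands beside the lung samples, and how lung RNA was isolated is not given in the sources used here. Biotin-labelled cRNA was hybridised, per the labels' protocols.

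The authors deposited, per tissue, a table with a bead-averaged signal per probe and array, an intensity on a linear scale that had not been normalized. Beside each signal the deposited tables give a detection p-value, a bead standard error (also an intensity) and a number of beads. The authors also deposited normalized values. For blood these deposited values are on a log2 scale: their slope against log2 of the raw signal was 0.994 above a signal of 2000 and 0.953 below 100 (air replicate 1). For lung the deposited values are a score on a variance-stabilised scale close to log2 at high signal: the slope was 1.05 above 2000 and 0.424 below 100, so small signals are compressed and the exact transform is not known. The column medians of the deposited values were 7.68 to 7.7 in lung and 6.87 to 6.9 in blood, and each column correlated with its own raw array at 0.9879 or more in lung and 0.998 or more in blood. These tables held exactly the probes with a detection p-value under 0.01 on at least 1 of the 12 arrays of the tissue, 11473 in lung and 7545 in blood. BeadStudio, lumi and limma are named in the submitters' processing notes, with no version and no order of use.

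The raw signals were used for the main analysis, in R 4.3.3 with limma 3.58.1. Within each tissue, neqc corrected the background (normal-exponential model, with the negative controls inferred from the detection p-values), added an offset of 16, quantile normalized the 12 arrays and took log2. Of 21792 probes, those with a detection p under 0.05 on at least 6 of the 12 arrays were tested: 11285 in lung and 7864 in blood. Silica was compared with air in each tissue alone by lmFit and eBayes, two-sided, with no covariate, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. Whether silica acted differently in the tissues was tested on each rat's lung minus blood log2 value, after neqc of the 24 arrays together, over the 7594 probes tested in both. Fold changes are silica over air unless they are called lower, and ± gives the standard error of a fitted log2 fold change or, beside a group mean, the SD over 6 rats. A probe undetected on every array of a group has only a bound there: its fold is the bright group's mean over, per array, the higher of the lowest detected signal and the probe's own signal, and is written with "at least".

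Before the data were examined, 37 gene lists were fixed, covering cell types of lung and blood, immune and metabolic pathways, and signs of tissue handling. The choice of tests, of the alternatives below and of the rule for naming genes was made at the same time. Each gene was represented by its tested probe with the highest mean, and lists with at least 4 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated from the data. By the rule, the text names in each tissue the 10 largest rises and the 10 largest falls past the threshold, or the 5 smallest p where none passed. From each list it names up to 4 members with the largest change past the threshold, or else the 2 most abundant. Of the genes this rule selects, some are not reported here. The genes named for lung were also read in blood, and for the difference between tissues the 5 with the smallest p were named. A list's score on an array is the mean log2 value of its tested genes, and scores were compared by exact permutation tests, two-sided, whose smallest p with 6 against 6 rats is 0.00216.

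Gene symbols are those of the deposited tables, updated through a RefSeq gene table of assembly GRCr8 that was used for names alone. Of 21792 probes, 16209 matched it (9918 by symbol, 1545 by gene identifier, 4746 by synonym). The other 5583 kept the symbol in the file, among them 9 that a spreadsheet had turned into dates. No genome of the array's design was at hand, so no positions are given.

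The procedure was tested on simulated data made from the real probe means and spreads, with 50 probes changed per fold size. The spreads were those of the raw signals before normalization, so the shares recovered may be too low. In the lung simulation (11933 probes tested) 12% of 1.25-fold, 48% of 1.5-fold, 68% of 2-fold and 84% of 4-fold changes were recovered, with 14 false calls. In the blood simulation (8226 probes) the shares recovered were 0%, 2%, 46% and 76%, with 1 false call. For the difference between tissues (8055 probes), 0%, 2.5%, 36.1% and 65.6% of the changed probes that entered the test were recovered, with 0 false calls. All 4 changed lists were recovered in each tissue, with 0 false lists in lung and 1 in blood. The simulated probes varied independently of each other, so these counts do not show how often lists of correlated genes pass by chance.

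The alternatives were no background correction, an offset of 50, cyclic loess or median scaling in place of quantile normalization, the authors' values, other filters on dim probes, array weights, a variance trend with robust moderation, the replicate number as a block, a fold of at least 1.5, an adjusted p under 0.01, and leaving out each array in turn. Leaving out 3 blood arrays and using a muscle score as a covariate in lung were added after the data had been seen. A BeadChip block was not run because the files do not name the chips, and the authors' values were not used for the difference between tissues because lung and blood are on different scales there. The number of arrays limits the precision of every comparison.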

Results

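The series compared lungs and peripheral blood of rats 32 weeks after a 5-day inhalation of crystalline silica, a respirable mineral dust, with those of rats that breathed filtered air. There were 24 arrays in 4 groups of 6: lung after air, lung after silica, blood after air and blood after silica. Between 11013 and 11733 of the 21792 probes were detected on a lung array, and between 7498 and 8469 on a blood array. The median raw signal per array was 66.1 to 74.9 in lung and 57.6 to 67.6 in blood. The median number of beads behind a probe was 36 to 42 in lung and 40 to 42 in blood. Arrays of a tissue correlated with each other at 0.9828 to 0.9965 in lung and 0.9789 to 0.997 in blood.

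In lung the first principal component held 49.8% of the variance and separated the groups, from -13.3 to -6.1 in the air rats and from 4.22 to 15.78 in the silica rats. In blood the first component (44.9%) did not. Blood of air rat 2 (18.61), silica rat 6 (13.55) and air rat 6 (9.38) lay at one end of it, and the other 9 rats lay between -6.12 and -0.88.

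The first comparison asked which transcripts differed in lung 32 weeks after silica. Lungs of silica rats held far more mRNA for Spp1 (osteopontin, a secreted phosphoprotein of matrix and activated macrophages) and Retnla (a resistin-like secreted protein). Spp1 went from 6.85 ± 0.22 to 10.85 ± 0.63 (log2, SD, n = 6 per group), a 15.9-fold rise, and Retnla from 9.47 ± 0.54 to 13.38 ± 0.32, a 15.1-fold rise. As lists, complement and acute phase genes were higher with them, and markers of alveolar type 1 cells, the flat cells of gas exchange, were lower. The largest fall was that of Nr1d1, a nuclear receptor of the circadian clock, from 9.39 ± 0.41 to 7.64 ± 0.58 (3.37-fold lower).

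Of 11285 probes tested in lung, limma called 1820 at the adjusted threshold, 857 higher and 963 lower after silica. Most calls were small: the median absolute log2 fold change was 0.26, and 50 called probes changed at least 2-fold, 47 of them upward. At an unadjusted p under 0.05 there were 3247 probes, where chance alone would give 564. For 915 probes (8.11%) every silica rat lay on one side of every air rat, where chance gives 0.216%.

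**Figure D1:**
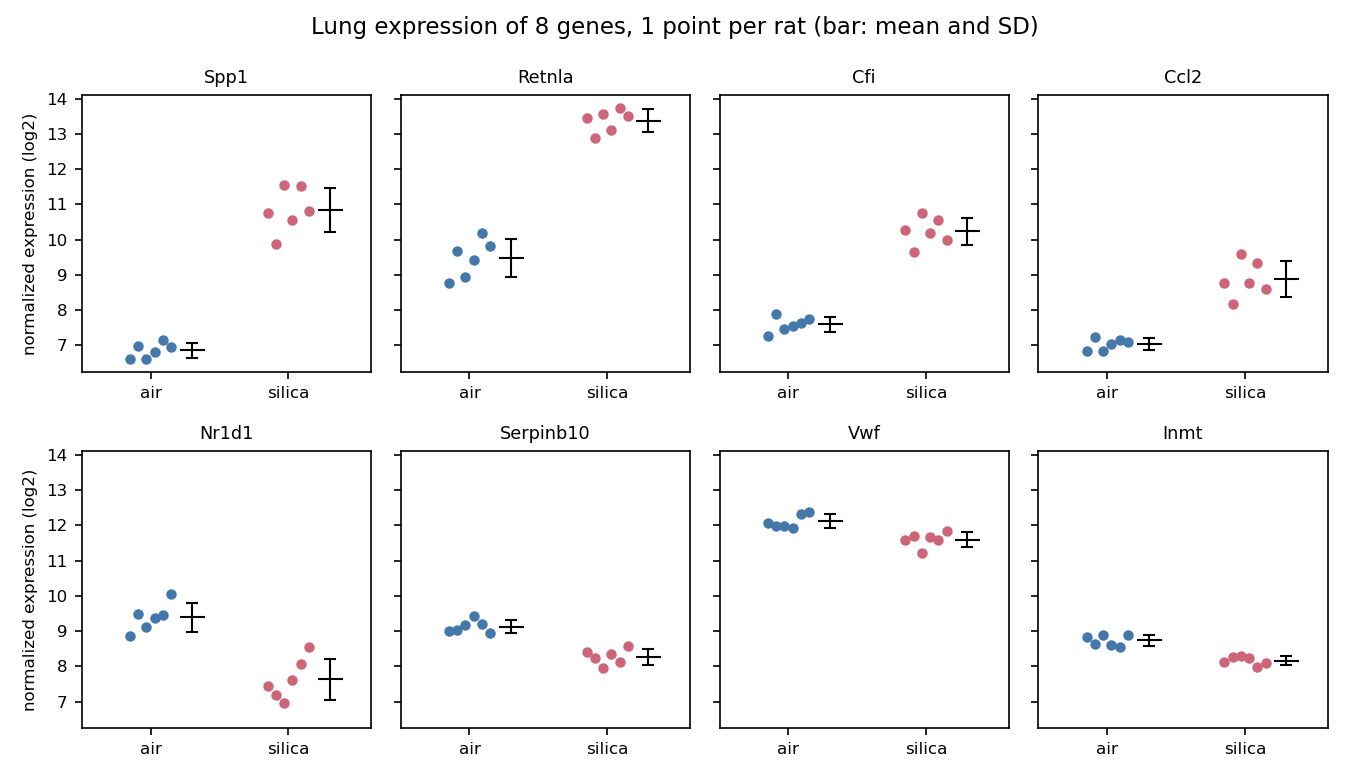
Normalized expression (log2) of 8 genes in lung, with 1 point per rat, 6 air and 6 silica rats, and a bar at the group mean with its SD. The silica rats lay between 9.87 and 11.5 for Spp1, all above the highest air rat at 7.16, and between 6.97 and 8.54 for Nr1d1, all below the lowest air rat at 8.85.

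Among the 10 largest rises, Spp1 (probe ILMN_1352642) had a log2 fold change of 3.99 ± 0.25 (adjusted p = 1.4e-05) and Retnla (ILMN_1362534) one of 3.91 ± 0.24 (adjusted p = 1.4e-05). Slc26a4, an anion exchanger, rose 10.6-fold (3.40 ± 0.26, adjusted p = 4.49e-05). Cfi, a protease that inactivates complement fragments, rose 6.24-fold (2.64 ± 0.17, adjusted p = 1.4e-05). Mmp12, the macrophage elastase, rose 6.13-fold (2.62 ± 0.37, adjusted p = 0.0012), and Ubd, a ubiquitin-like modifier, rose 5.66-fold (2.50 ± 0.36, adjusted p = 0.00129). Lpo, the secreted lactoperoxidase, was undetected in all 6 air lungs and detected in all 6 silica lungs. Its means were 6.45 and 8.85 (log2), at least 5.22-fold higher (adjusted p = 0.00019). The immunoglobulin heavy chain probe IGH-1A_PREDICTED rose 5.18-fold (adjusted p = 0.000512). The other 2 of the 10 carry only locus names, LOC497762 (9.17-fold) and LOC500172 (5.15-fold). For all 10 of these genes each silica rat lay above every air rat.

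Falls were smaller. After Nr1d1 (fell by 1.75 ± 0.27 on the log2 scale, adjusted p = 0.00175), Dlk1, a membrane protein related to Notch ligands, was 2.18-fold lower (adjusted p = 0.0177). Serpinb10, a serine protease inhibitor, was 1.81-fold lower (adjusted p = 0.000729), and Akr1c19, an aldo-keto reductase, was 1.77-fold lower (adjusted p = 0.000283). Gpihbp1, which anchors lipoprotein lipase to capillary endothelium, was 1.76-fold lower (adjusted p = 0.00292). Ahsp, which stabilises free alpha-globin, was 2.06-fold lower (adjusted p = 0.0232, and 0.0544 without silica replicate 3). Igfbp6, a binding protein of insulin-like growth factors, was 1.87-fold lower (adjusted p = 0.0242). That call ended without air replicate 3 (0.0551), silica replicate 3 (0.0565) or silica replicate 5 (0.0526). Upk3b, a uroplakin, was 1.86-fold lower (adjusted p = 0.0368), but 8 of the 12 fits without 1 array put it at 0.051 to 0.0826 (without air replicates 3 to 6 or silica replicates 1, 3, 4 or 5). LOC686725 was 1.81-fold lower (adjusted p = 0.047), and 9 such fits put it at 0.064 to 0.101 (without air replicates 3 to 6 or silica replicates 1 to 5).

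Of the 37 gene lists, 21 passed camera's test in lung, 17 upward and 4 downward. With an estimated correlation 3 of these calls held: complement, the acute phase and antimicrobial proteins, and the alveolar type 1 cell markers. For each of the other 18 lists past the test, the adjusted p with an estimated correlation is given beside it. Counts of members are those of the main fit, and some members not named here lost their calls in fits without 1 array. Such members were in the alveolar type 1, alveolar type 2, fibroblast and chemokine lists, among others.

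**Figure D2:**
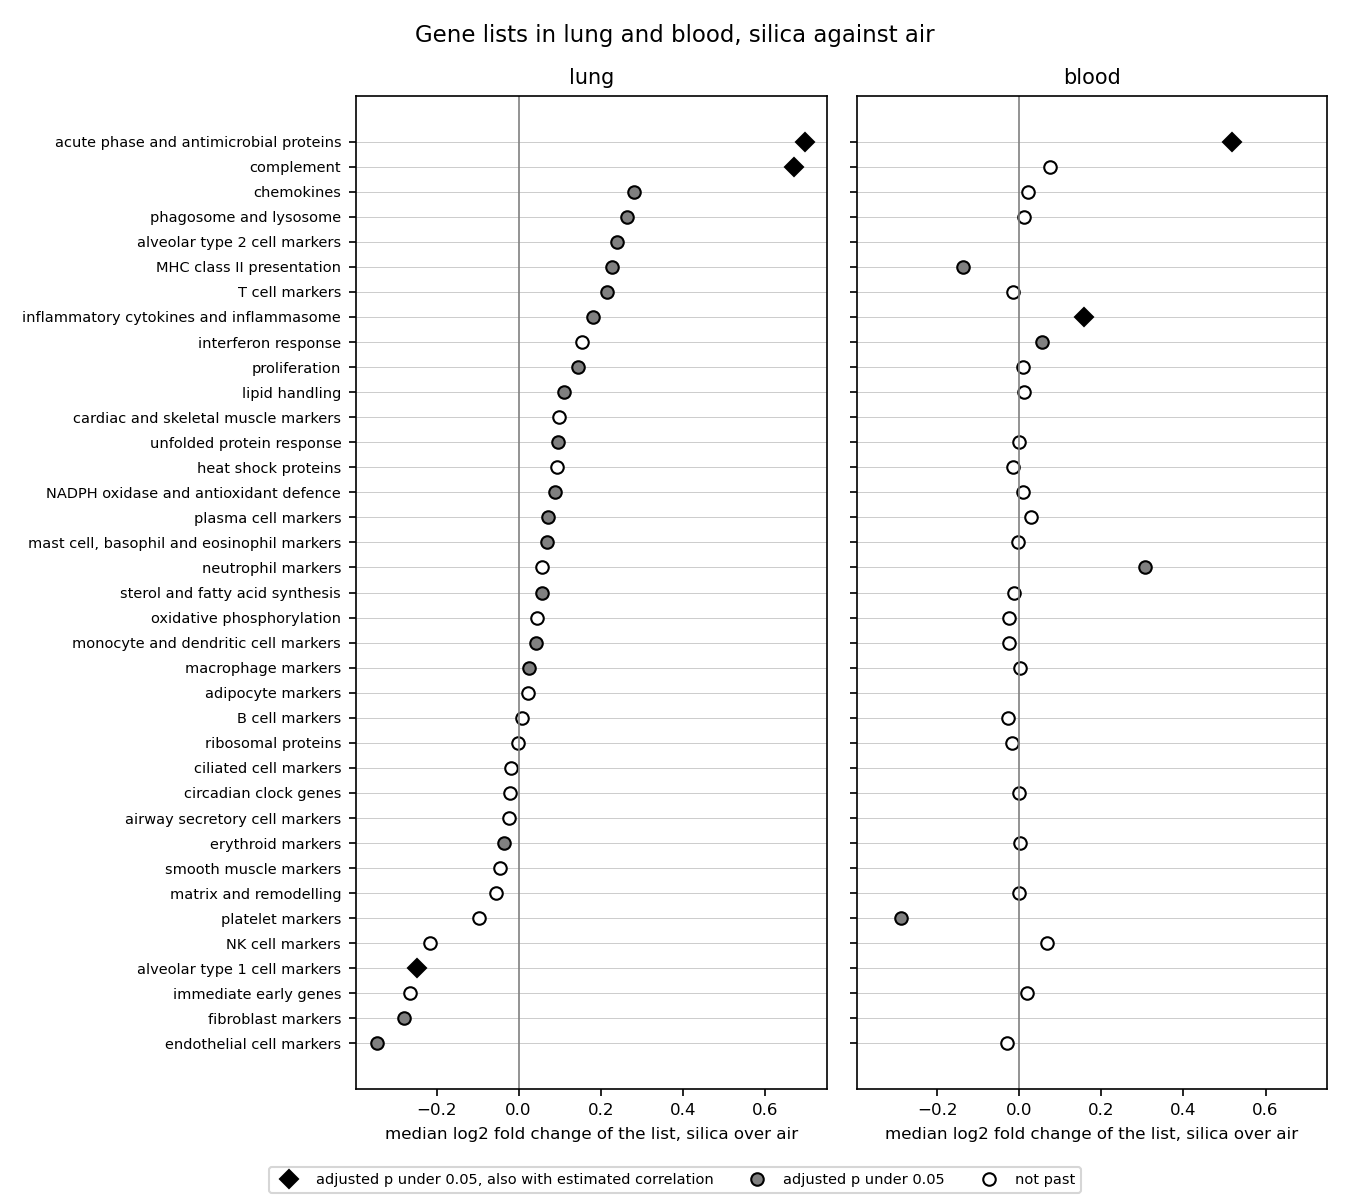
Median log2 fold change (silica over air) of the tested genes of each list, lung on the left and blood on the right. Grey circles mark lists past the adjusted threshold with the preset correlation, black diamonds those past it with an estimated correlation as well, and open circles the rest. In lung the medians run from -0.34 (endothelial cell markers) to 0.70 (acute phase and antimicrobial proteins), and 8 of the 37 lists had too few tested genes in blood.

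Complement genes, which tag particles and cells for removal, rose together: 11 of 13 passed, all upward (11 also when adjusted over the list alone). Beside Cfi, C4b rose 1.8-fold (adjusted p = 0.0014), C2 rose 1.78-fold (adjusted p = 0.00184) and C1s rose 1.69-fold (adjusted p = 0.00107). The list's adjusted p was 5.54e-11, and 0.0162 with an estimated correlation. Of 9 genes for acute phase and antimicrobial proteins, 6 rose (7 adjusted over the list alone) and the other 3 did not pass. Lcn2, an iron-scavenging lipocalin, rose 3.71-fold (1.89 ± 0.26), and Hp, the haemoglobin-binding haptoglobin, rose 2.48-fold (1.31 ± 0.12). The protease inhibitor Slpi rose 2.26-fold (adjusted p = 0.0119). Orm1, undetected in every air lung, had means of 6.47 and 7.30 and was at least 1.77-fold higher (adjusted p = 0.00264). The list's adjusted p was 6.21e-07, and 0.0451 with an estimated correlation.

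Chemokine transcripts rose in number: 15 of 24 went up, 1 went down and 8 did not pass (16 up and 2 down adjusted over the list alone). The monocyte attractant Ccl2 rose 3.58-fold (1.84 ± 0.20, adjusted p = 0.000392), the lymphocyte attractant Ccl19 rose 3.34-fold (adjusted p = 0.0198) and the interferon-inducible Cxcl11 rose 2.71-fold (adjusted p = 0.00906). The list's adjusted p was 1.74e-07 (adjusted p = 0.0777 with an estimated correlation). Of 12 inflammatory cytokine and inflammasome genes, 3 rose and 9 did not pass (4 rose adjusted over the list alone). These were the decoy receptor Il1r2 (1.95-fold), the receptor antagonist Il1rn (1.6-fold) and Il1b (1.57-fold), so 2 of the 3 are known to restrain interleukin-1. That list had an adjusted p of 0.00168 (adjusted p = 0.0809 with an estimated correlation).

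Phagocyte genes rose in part. In the phagosome and lysosome list 8 of 17 rose and 1 fell (10 and 2 adjusted over the list alone), among them the cysteine proteases Ctsk (2.12-fold) and Ctss (1.47-fold), the membrane glycoprotein Gpnmb (1.72-fold) and the proton pump subunit Atp6v0d2 (1.47-fold). Its adjusted p was 6.88e-06 (adjusted p = 0.16 with an estimated correlation). Of 9 macrophage markers, 3 rose (3 adjusted over the list alone): Cd68 1.72-fold (adjusted p = 0.00103), Lgals3 1.46-fold and Itgax 1.06-fold. That list lay just past the threshold (adjusted p = 0.0477; adjusted p = 0.264 with an estimated correlation). Its call ended without air replicate 1 (0.0622), 2 (0.0574) or 3 (0.0906) or silica replicate 4 (0.0644) or 5 (0.0638). Of 11 monocyte and dendritic cell markers, 3 rose (4 adjusted over the list alone): the endotoxin co-receptor Cd14 1.64-fold, Cd83 1.42-fold and the integrin Itgam 1.19-fold (list adjusted p = 0.0019; adjusted p = 0.201 with an estimated correlation). Of 9 neutrophil markers only S100a8 passed, at 2.2-fold (adjusted p = 0.00544), and 4 rose adjusted over the list alone. The neutrophil list did not pass (adjusted p = 0.0512), but did without air replicate 2 (0.0324), 3 (0.0359) or 4 (0.0485) or silica replicate 2 (0.0239), 4 (0.0462) or 5 (0.0412). It also passed with the authors' values (0.0477), without background correction (0.0405) and with no filter on dim probes (0.0109).

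Of 8 MHC class II genes 5 rose (5 adjusted over the list alone), with RT1-Db1 at 1.68-fold, RT1-Ba at 1.65-fold and the invariant chain Cd74 at 1.49-fold (list adjusted p = 4.67e-05; adjusted p = 0.138 with an estimated correlation). Of 14 T cell markers 5 rose (12 adjusted over the list alone), led by the receptor adaptor Lat at 1.62-fold (adjusted p = 0.0158; list adjusted p = 2.01e-05; adjusted p = 0.201 with an estimated correlation). Of 7 plasma cell markers 3 rose (3 adjusted over the list alone), with the antibody joining chain Jchain at 2.79-fold (1.48 ± 0.18, adjusted p = 0.000616). That list's adjusted p was 0.00231 (adjusted p = 0.0655 with an estimated correlation). None of 6 B cell markers passed (list adjusted p = 0.727). Bank1 and Cd79b, its most abundant members, had log2 fold changes of -0.11 ± 0.07 and -0.01 ± 0.03. In the mast cell, basophil and eosinophil list 5 of 11 rose and 1 fell (5 and 1 adjusted over the list alone), with the protease Mcpt10 at 1.2-fold (list adjusted p = 0.00748; adjusted p = 0.201 with an estimated correlation).

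Cell cycle genes rose. Of 15 proliferation genes 9 passed, all upward (12 adjusted over the list alone). The mitotic cyclin Ccnb2 rose 1.58-fold (0.66 ± 0.08, adjusted p = 0.000501), the replication helicase subunit Mcm6 rose 1.51-fold and the kinase Cdk1 rose 1.38-fold. The list's adjusted p was 3.44e-09 (adjusted p = 0.0655 with an estimated correlation).

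Among resident cells of the lung, endothelial markers fell: 8 of 10 passed, all downward (10 adjusted over the list alone). Vwf, the platelet-binding von Willebrand factor, was 1.43-fold lower (adjusted p = 0.00964), the endothelin receptor Ednrb was 1.41-fold lower (adjusted p = 0.000637) and the angiopoietin receptor Tek was 1.37-fold lower (adjusted p = 0.00131). That list's adjusted p was 7.8e-08 (adjusted p = 0.0655 with an estimated correlation). Of 9 fibroblast markers 6 fell (7 adjusted over the list alone), with the methyltransferase Inmt 1.49-fold lower and the growth factor receptor Pdgfra 1.31-fold lower (list adjusted p = 0.000177; adjusted p = 0.0655 with an estimated correlation). Of 10 alveolar type 1 cell markers 6 fell (9 adjusted over the list alone). Some of these calls, of members not named here, ended in fits without 1 array. Cav1, of caveolae, was 1.31-fold lower (adjusted p = 0.00934) and Ager, a pattern recognition receptor, was 1.18-fold lower (adjusted p = 0.0067). The list's adjusted p was 0.000113, and 0.0413 with an estimated correlation.

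Alveolar type 2 cell markers, of the surfactant-making cells, went the other way. Of 11, 5 rose (8 up and 1 down adjusted over the list alone), with the mucin Muc1 at 1.65-fold (adjusted p = 0.00353) and Lpcat1, of surfactant lipid synthesis, at 1.41-fold (adjusted p = 0.00482). That list's adjusted p was 0.0011 (adjusted p = 0.201 with an estimated correlation). Of 12 lipid handling genes 5 rose and 1 fell (6 and 1 adjusted over the list alone): the fatty acid carrier Fabp4 rose 2.55-fold (adjusted p = 0.0013), the lipid droplet protein Plin2 rose 1.21-fold, and the sterol sensor Nr1h3 was 1.09-fold lower. The list's adjusted p was 0.00192 (adjusted p = 0.201 with an estimated correlation). Of 17 sterol and fatty acid synthesis genes 3 rose (5 adjusted over the list alone), with Dhcr7 at 1.28-fold (list adjusted p = 0.00231; adjusted p = 0.201 with an estimated correlation).

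Among 20 genes of the NADPH oxidase and of antioxidant defence, 8 rose and 3 fell (9 and 3 adjusted over the list alone). The oxidase subunit Ncf1 rose 2.2-fold (1.14 ± 0.17), haem oxygenase Hmox1 rose 2.12-fold (1.09 ± 0.14), the metallothionein Mt1 rose 1.92-fold (0.94 ± 0.06) and mitochondrial superoxide dismutase Sod2 rose 1.76-fold (0.81 ± 0.08). That list's adjusted p was 0.00457 (adjusted p = 0.138 with an estimated correlation). Of 13 genes of the unfolded protein response 2 rose (2 adjusted over the list alone), Sdf2l1 (log2 fold change 0.33 ± 0.07) and Ddit3 (1.16-fold) (list adjusted p = 0.0121; adjusted p = 0.201 with an estimated correlation). Of 11 erythroid markers 2 fell (4 adjusted over the list alone), Ahsp and Bpgm, the latter 1.22-fold lower (list adjusted p = 0.0227; adjusted p = 0.201 with an estimated correlation). Ahsp did not pass without silica replicate 3 (0.0544). Bpgm did not without air replicates 3 to 6 or silica replicates 3 to 5 (0.0638 to 0.0824).

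Matrix and remodelling genes split, and that list did not pass (adjusted p = 0.526). Of 21, 5 rose and 7 fell (5 and 8 adjusted over the list alone). Beside the rises of Spp1 and Mmp12, the collagen chain Col6a1 was 1.41-fold lower (fell by 0.50 ± 0.06 on the log2 scale, adjusted p = 0.000501) and periostin (Postn) was 1.36-fold lower (adjusted p = 0.00759). The median log2 fold change of the list was -0.05 and its mean 0.22, while the test pointed down. Clock genes split too (adjusted p = 0.854): of 9, 2 rose and 1 fell (2 and 2 adjusted over the list alone). Beside the fall of Nr1d1, Bhlhe41, a repressor in the clock, rose 1.6-fold (adjusted p = 0.0114). Cry1 rose too (log2 fold change 0.32 ± 0.09, adjusted p = 0.0376), but 7 of the 12 fits without 1 array put it at 0.0622 to 0.0842 (without air replicates 4 to 6 or silica replicates 1 to 4).

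The other lists did not pass in lung. Interferon response genes (adjusted p = 0.0517) had 1 member up, Isg20, and 2 down, Mx2 and Ifi27, of 19. Oxidative phosphorylation (adjusted p = 0.0567) had 2 of 15 up, Cox5a and Ndufs3, and platelet markers (adjusted p = 0.0737) 2 of 6 down, Gp1bb and Clec1b. Heat shock proteins (adjusted p = 0.219) had 1 of 6 up, Dnajb1, and immediate early genes (adjusted p = 0.721) 2 of 12 up, Egr2 and Atf3. Smooth muscle markers (adjusted p = 0.454) had 1 of 8 down, Smtn. NK cell markers (adjusted p = 0.533) had 1 of 8 up, Ctsw. Ciliated cell markers (adjusted p = 0.727) had Tekt2 up and Tppp3 down of 9. Airway secretory markers (adjusted p = 0.796) had 1 of 7 down, Aldh1a1. Ribosomal proteins (adjusted p = 0.818) had 1 of 21 down, Rpl19. None of 5 adipocyte markers (adjusted p = 0.63) and none of 11 cardiac and skeletal muscle markers (adjusted p = 0.413) passed. Adjusted over each list alone, the counts were 3 up and 2 down for interferon, 4 down for platelets, 2 up and 1 down for heat shock, and unchanged for the other 9. The heart muscle genes Myl7 (7.99 ± 1.97 in air, 8.74 ± 1.91 in silica) and Myh6 (7.77 ± 1.80 and 8.54 ± 1.74) differed widely between rats of the same group. Median, mean and test also differed in sign for the ciliated, airway secretory, ribosomal, B cell and adipocyte lists.

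Some calls in these lists lay near the threshold. Gp1bb (log2 fold change -0.31, and -0.26 to -0.33 in these fits) did not pass in 9 of the 12 fits without 1 array (0.056 to 0.101; without air replicates 1 to 4 or silica replicates 1 to 4 or 6), and Clec1b (-0.17, and -0.14 to -0.18) did not in 8 (0.0517 to 0.0695; without air replicates 2 to 4 or silica replicates 1 or 3 to 6). Ifi27 did not pass without air replicates 2, 3 or 5 or silica replicates 1, 5 or 6 (0.0503 to 0.0627). Egr2 did not without air replicate 3 (0.0584) or 5 (0.0562), nor Ctsw without silica replicate 4 (0.0508). The interferon list passed upward without air replicates 2, 3 or 4 or silica replicates 1, 2 or 6 (0.0147 to 0.0478), and oxidative phosphorylation without air replicate 2 (0.0195), air replicate 3 (0.0277) or silica replicate 6 (0.0264). The interferon list also passed with the authors' values (0.0482), without background correction (0.0415) and with no filter on dim probes (0.0124), oxidative phosphorylation with no filter (0.0285), and the platelet list, downward, without background correction (0.0448). Without air replicate 6 the NK cell (0.0114) and platelet (0.0256) lists passed downward, and without air replicate 3 the muscle list passed upward (0.0224).

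With median scaling in place of quantile normalization, which left a residual SD of 0.124 where the main analysis had 0.073, the lung count was 170 probes (125 higher, 45 lower). The 10 largest rises, Nr1d1, Serpinb10, Akr1c19 and Gpihbp1 were among them, and Dlk1, Ahsp, Igfbp6, Vwf, Ednrb, Tek, Inmt, Pdgfra, Cav1 and Ager were not. Log2 fold changes of dim probes depended on the background step: without it those of Orm1 (0.82), Itgam (0.25), Mcpt10 (0.26) and Itgax (0.08) were 1.75, 0.62, 0.72 and 0.27.

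The second comparison asked whether blood of the same rats differed. No single transcript passed limma's test in blood, but the inflammatory cytokine and the acute phase and antimicrobial genes were higher after silica as lists. Slpi, the inhibitor of neutrophil elastase, was at 10.21 ± 0.25 in air and 10.97 ± 0.23 in silica blood (log2, SD, n = 6 per group), 1.69-fold higher. S100a8, a calcium-binding protein of neutrophils, was at 11.72 ± 0.28 and 12.34 ± 0.23, 1.53-fold higher, and Il1b was 1.42-fold higher, none of them past the adjusted threshold.

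Of 7864 probes tested in blood, limma called 0, and the smallest adjusted p was 0.0893. At an unadjusted p under 0.05 there were 680 probes (362 higher, 318 lower), where chance would give 393. The groups did not overlap for 47 probes (0.598%, against 0.216% by chance). The 5 smallest p, each with an adjusted p of 0.0893, were those of LOC313824 (log2 fold change 0.40 ± 0.06), Ppp1r3b, a glycogen-targeting phosphatase subunit (0.33 ± 0.05), Mrps18b, of the mitochondrial ribosome (-0.30 ± 0.05), Zfp532 (0.11 ± 0.02) and the transcription factor subunit Junb (0.63 ± 0.10). All 6 silica rats lay above every air rat for LOC313824, Ppp1r3b, Zfp532 and Slpi, and below for Mrps18b. For Slpi (0.76 ± 0.13) the adjusted p was 0.115, for S100a8 (0.61 ± 0.14) 0.225 and for Il1b (0.51 ± 0.13) 0.261. Among other settings, an offset of 50, cyclic loess, median scaling, no filter on dim probes and the strict filter gave 0. Array weights gave 4, a variance trend with robust moderation 5, no background correction 6 and the authors' values 7, with Slpi and LOC313824 in each of these 4. Without silica replicate 4 there were 18 probes, among them Junb (0.000375), Zfp532 (0.00414), Ppp1r3b (0.00982), LOC313824 (0.0219), Mrps18b (0.0411) and Slpi (0.0429). LOC313824 also passed without silica replicate 2 (0.0117). The fold of the dim probe of Zfp532 depended on the background step: its log2 fold change was 0.35 without background correction and 0.39 with the authors' values.

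Of 29 lists with enough tested genes in blood, 6 passed camera's test, 4 upward and 2 downward. With an estimated correlation 2 held, the inflammatory cytokines and the acute phase proteins. All 13 inflammatory cytokine and inflammasome genes were higher (0 passed alone, 6 adjusted over the list alone), with a list adjusted p of 8.06e-08, and 0.0123 with an estimated correlation. All 4 acute phase and antimicrobial genes were higher (0 passed, 2 adjusted over the list alone), Slpi and the peptidoglycan-binding Pglyrp1 (1.64-fold) the most abundant of them, with a list adjusted p of 2.38e-05, and 0.0123 with an estimated correlation. All 8 neutrophil markers were higher (0 passed, 4 adjusted over the list alone), among them S100a8 and the collagenase Mmp8 (log2 fold change 0.32 ± 0.12; list adjusted p = 1.28e-06; adjusted p = 0.0631 with an estimated correlation). Of 19 interferon response genes 13 were higher (0 passed, 4 adjusted over the list alone; list adjusted p = 0.000831; adjusted p = 0.15 with an estimated correlation). Its most abundant members, Irf7 and Ifit1, had log2 fold changes of 0.00 ± 0.14 and 0.03 ± 0.09.

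Platelet markers were lower in blood as a list, 7 of 7 with 0 past the test alone or adjusted over the list alone (list adjusted p = 0.0143; adjusted p = 0.366 with an estimated correlation). Pf4 and Gp1bb, its most abundant members, had log2 fold changes of -0.06 ± 0.08 and -0.10 ± 0.12, with Pf4 (14.06 in air rats) near the top of the scale, where folds can be compressed. The platelet call ended without air replicate 1 (0.0646), 3 (0.0647) or 6 (0.0618) or silica replicate 6 (0.127). MHC class II genes were higher in lung as a list (adjusted p = 0.138 there with an estimated correlation). In blood the list was lower, 7 of 7 with 0 past the test alone or adjusted over the list alone (list adjusted p = 0.0173; adjusted p = 0.15 with an estimated correlation). RT1-Da had a log2 fold change of -0.18 ± 0.10 and RT1-Db1 one of -0.30 ± 0.16. That call ended without air replicate 3 (0.0616) or silica replicate 6 (0.0711). The other 23 lists had adjusted p from 0.0555 (immediate early genes) to 0.949 (clock genes) and medians from -0.03 to 0.08. Without 1 array some of these passed: immediate early genes without air replicate 5 (0.0434), air replicate 6 (0.0372) or silica replicate 4 (0.0108), and chemokines without silica replicate 1 (0.0253) or 3 (0.0449). Complement (upward, 0.0346) and endothelial markers (downward, 0.0355) passed without air replicate 2, and NK cell markers (upward) without silica replicate 1 (0.00391). Immediate early genes, a sign of tissue handling, also passed upward with the authors' values (0.0353), without background correction (0.0352), with no filter on dim probes (0.0436) and without air replicates 2 and 6 and silica replicate 6 together (0.0213). In that last setting complement passed upward (0.0124) and endothelial markers downward (0.0321). Among the 23, T cell markers had an adjusted p of 0.373, NK cell markers 0.257 and erythroid markers 0.72. Median, mean and test differed in sign for the heat shock, mast cell and clock lists.

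**Figure D3:**
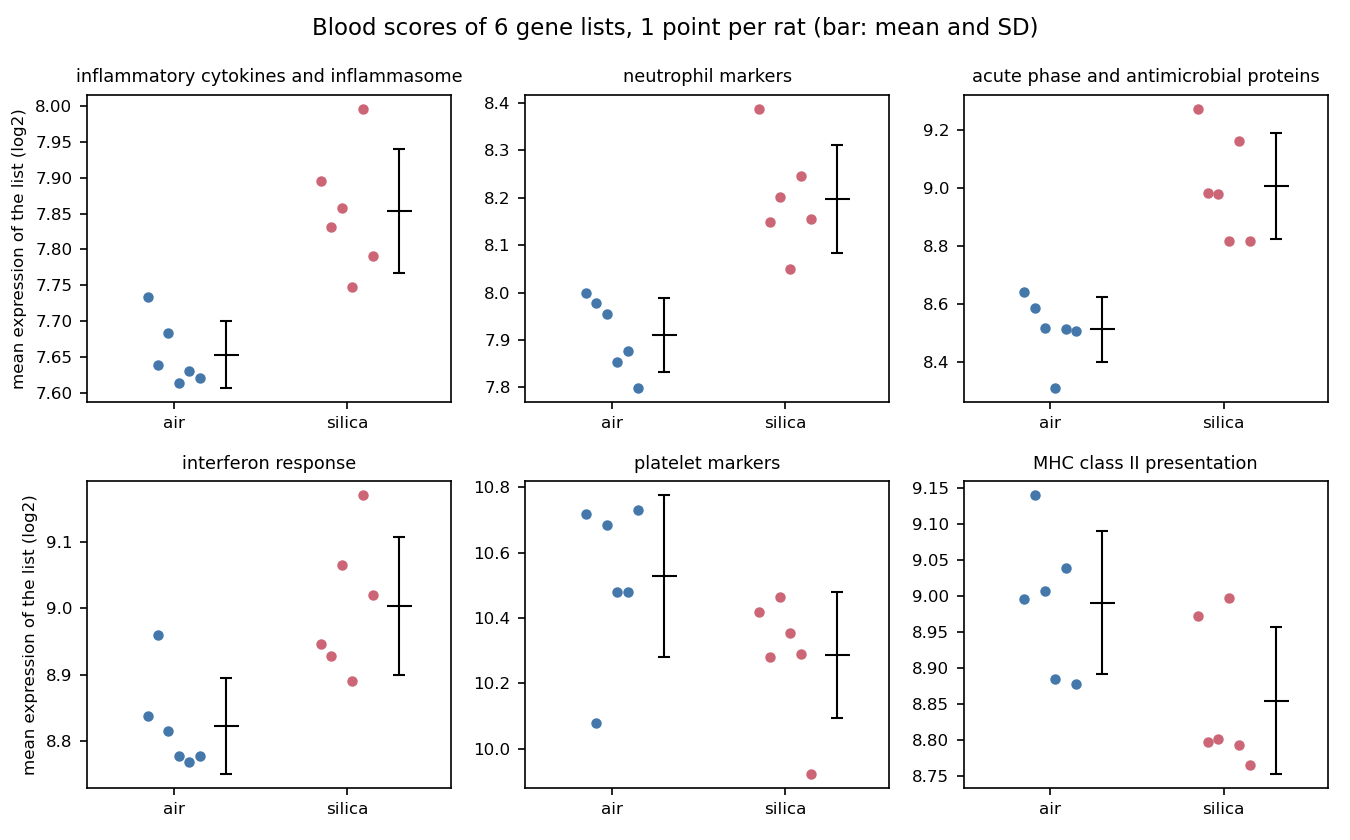
Score (mean log2 value of the tested genes) of the 6 lists past the test in blood, with 1 point per rat, 6 air and 6 silica rats, and a bar at the group mean with its SD. The vertical scales differ between panels and do not start at 0. For the inflammatory cytokine list the means were 7.65 ± 0.05 in air and 7.85 ± 0.09 in silica rats.

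The third comparison asked whether the effect of silica differed between lung and blood of the same rats. Retnla differed most: after joint normalization its log2 fold change was 4.68 ± 0.25 in lung and 0.09 ± 0.12 in blood, a difference of 4.59 ± 0.23 (adjusted p = 1.5e-07). Chi3l1, a chitinase-like protein of macrophages and neutrophils, had 1.70 ± 0.14 in lung and 0.32 ± 0.09 in blood (difference 1.37 ± 0.13, adjusted p = 0.000196). Chst1, a sulfotransferase, differed by 0.93 ± 0.09 (adjusted p = 0.000196) and Mt1 by 0.86 ± 0.09 (adjusted p = 0.000238). Reck, an inhibitor of matrix metalloproteinases, had -0.60 ± 0.06 in lung and 0.00 ± 0.04 in blood (difference -0.60 ± 0.07, adjusted p = 0.000635). Reck lay at the floor of the blood arrays (6.43), where no fall can show, so its difference mirrors the lung fold.

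Of 7594 probes tested in both tissues, limma called 266, with 170 effects higher and 96 lower in lung than in blood. At an unadjusted p under 0.05 there were 1245. Of 76 genes named for lung and tested here, 28 passed. Ubd (1.69), Ccl2 (1.49), Hp (1.19), Ncf1 (1.13), Cd68 (1.05) and Hmox1 (0.80) had higher log2 effects in lung, as had the MHC class II genes RT1-Db1 (1.17), RT1-Ba (0.95) and Cd74 (0.80). A rise of a probe dim in blood can be compressed, so part of such a difference may be one of scale. For Ubd the log2 fold change in blood was 0.48 after joint normalization and 0.15 with blood normalized alone. Nr1d1 (-1.44) and Serpinb10 (-0.69) also passed, but with blood means of 6.45 and 6.60 in air rats they lay at or near the floor, where blood can show little or no fall, so a different effect of silica is not shown for them. With each tissue normalized on its own the count was 510, of which 227 were shared with the same direction, and the calls of Cd68 (adjusted p = 0.0623), S100a8 (0.163), Jchain (0.114) and Cox5a (0.0785) ended. Their differences were then 0.90, 0.53, 1.03 and 0.42, against 1.05, 0.90, 1.51 and 0.45 after joint normalization. The size of a difference thus depended on the normalization too. Without silica rat 6 the count was 410.

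The last comparison asked whether transcripts changed in lung moved the same way in blood. Of 1193 lung calls tested in blood, 681 (57.1%) had the same direction there: 364 of 678 higher ones (53.7%) and 317 of 515 lower ones (61.6%). Among probes not called in lung, 48.5% were higher and 51.5% lower in blood. When the blood rats were split anew with the lung calls kept, 27 of 100 splits, the real one included, gave as many of one direction (highest other 737), so this count is not beyond chance. That test was chosen after the overlap was seen. Across probes, log2 fold changes of lung and blood correlated at 0.104, and 50 of 100 splits of the rats gave a correlation as high (highest other 0.266).

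Since limma called 0 probes in blood, an unadjusted p under 0.01 was used there for shared genes. The same splits were applied to these counts, a test again chosen after the overlap was seen. Of the lung rises, 37 were also higher in blood at that level, and 3 of the 100 splits, the real one included, gave as many (highest other 40, median of the others 3). They included Slpi, S100a8, Il1b, Il1r2, Ctss, Ubd, the elastase inhibitor Serpinb1a, the platelet-activating factor receptor Ptafr and the signalling adaptor Myd88, the last 3 chosen after their values were seen. Of the lung falls, 9 were also lower in blood, and 11 of the 100 splits gave as many (highest other 21), so chance is not excluded for these.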

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

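Chosen only after the result was seen were the tests of dilution, the test of the hour of collection and the splits of the blood rats for the overlap. The tests of quantile normalization, of the 3 blood arrays apart and of the neutrophil share, and the other splits of the rats, were planned before their results were seen, though which 3 arrays lay apart was read from the data.

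In lung, endothelial, alveolar type 1 and fibroblast markers were lower as lists while alveolar type 2 markers were higher (adjusted p with an estimated correlation 0.0655, 0.0413, 0.0655 and 0.201). Quantile normalization is argued against as the source of the endothelial fall by median scaling, under which the endothelial median was -0.296, against -0.344 in the main analysis. That was the highest median over cyclic loess, median scaling and the authors' values. Cyclic loess also matches arrays over the range of signal, and how the authors normalized is not known, so these tell less. Dilution of every resident cell type by added immune cells would not raise the alveolar type 2 score, which was higher by 0.269 ± 0.0668 (exact permutation p = 0.00433, and 0.0303 when multiplied by the 7 resident lists). That rise was part of the pattern when the test was chosen. The test therefore leaves open whether dilution lowered the endothelial, alveolar type 1 and fibroblast markers. Dilution was tested in 2 other ways: a test that all 7 lists shifted alike gave an exact permutation p of 0.331, and a contrast of the lists grouped by their direction (0.351 ± 0.0662) decides nothing because of that grouping. With median scaling the single-gene calls of the endothelial and fibroblast genes named above ended, while the list medians were -0.296 and -0.23 (against -0.344 and -0.278) and the residual SD was 0.124 (against 0.073).

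In blood, the inflammatory cytokine, acute phase, neutrophil and interferon lists were higher with no probe past the adjusted threshold. With an estimated correlation the neutrophil (0.0631) and interferon (0.15) lists did not pass, and the other 2 did (0.0123 each). The 3 arrays apart on the first component (air 2, air 6 and silica 6) are argued against as the source: 4 of the 4 lists stayed past the test without them. A higher share of neutrophils as the whole of the rise cannot be told apart from a change within cells: with the neutrophil score (0.288 ± 0.0564 higher) as a covariate, the shift of the other 3 lists went from 0.292 ± 0.0509 to 0.0819 ± 0.0602. Both 0 and a remaining rise lie within 2 SE of it, and cell counts were not analysed here.

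Nr1d1 was lower and Bhlhe41 and Cry1 were higher in silica lung. Dilution by added immune cells cannot be told apart for Nr1d1: its interval ended at -1.16, but it was picked as the largest fall, and tested with all probes for a change beyond 0.449, the most that the endothelial score allows, it had an adjusted p of 0.0929. A different hour of collection in the 2 groups cannot be told apart from an effect of silica: the mean of the clock output genes tested in blood shifted by 0.0526 (SE 0.0273, exact permutation p = 0.0887) and that in lung by -0.116 (SE 0.075, exact permutation p = 0.162). In lung 4 of 4 such genes were lower and in blood 1 of 3, and the labels give no hour. The blood score of all clock genes tested was 6.64 in air rats, near the floor, where a fall can show little.

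Other splits of the 12 rats into 6 and 6, of which 100 were drawn from 462, tested whether chance could give as much. Chance can be excluded for the 1820 lung probes (1 split, the real one, gave as many; highest other 11) and for the 266 probes whose effect differed between tissues (1 split; highest other 6). In blood the real count of 0 is matched by all 100 splits by definition (highest other 6), so that comparison says nothing about chance. It cannot be excluded for the number of lists past the test, 21 in lung (5 splits with as many; highest other 21) and 6 in blood (7 splits; highest other 12), although the median over the other splits was 8 lists in lung and 1 in blood. Splits that keep most silica rats together can carry part of any silica difference, but splits that divide them evenly were not looked at alone. The correlation estimated in lung was 0.543 for T cell and 0.325 for endothelial markers, far above the preset 0.01, though 0.0172 for alveolar type 1 markers. Adjusted p with the preset correlation may therefore be too small for some lists. These counts cannot show how many lists chance alone gives.

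A single rat stood apart from the other 5 of its group in 32 of 514 groups of values, by a gap over range above Dixon's 95% critical value for 6, where chance gives about 1 in 20 groups. Reported here are, in lung, low values of air rat 6 for S100a8 (0.737), of air rat 2 for Derl3 (0.661) and Mcpt10 (0.652), of air rat 4 for Lipe (0.716), of air rat 1 for Nr1h3 (0.814), of silica rat 2 for Lpcat1 (0.778), of silica rat 3 for Cav1 (0.633) and of silica rat 6 for Ccnb2 (0.651). High lung values were those of air rat 2 for LOC500172 (0.678), of silica rat 6 for Smtn (0.693), and of silica rat 4 for Il1rn (0.813), Nr1h3 (0.641) and Egr2 (0.762). Among lung list scores, air rat 6 was low for T cell (0.631) and NK cell (0.652) markers, and silica rat 6 was low for ribosomal proteins (0.642) and oxidative phosphorylation (0.672).

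In blood, silica rat 6 was apart 7 times: on the first component (0.737), high for Cd68 (0.628), Vwf (0.638), Gclm (0.688) and Cry1 (0.661), and low for Pf4 (0.781) and the platelet list (0.661). Blood of silica rat 4 was low for Junb (0.78) and high for Rplp0 (0.651), and that of silica rat 5 was high for Cd36 (0.719). Blood of air rat 2 was low for Pltp (0.763) and high for RT1-Db1 (0.701) and the interferon list (0.64), and that of air rat 6 was low for Irf7 (0.643).

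The effect of silica, tested as a difference between tissues, was higher in lung than in blood (log2) for Retnla (4.59), LOC500172 (2.57), IGH-1A_PREDICTED (2.4), Ubd (1.69), Jchain (1.51), Ccl2 (1.49), Chi3l1 (1.37), Hp (1.19), RT1-Db1 (1.17), Ncf1 (1.13), Cd68 (1.05), RT1-Ba (0.946), Chst1 (0.933), S100a8 (0.896), Sod2 (0.896), Mt1 (0.858), C4b (0.837), Cd83 (0.811), Hmox1 (0.804), Cd74 (0.803), Lpcat1 (0.758), Bhlhe41 (0.68), Mcm6 (0.547), Ccnb2 (0.482), Cox5a (0.449) and RT1-Da (0.438). The difference was negative for Nr1d1 (-1.44), Ahsp (-0.897), Serpinb10 (-0.688), Reck (-0.598) and Tppp3 (-0.496), but this does not show that silica acted differently: in blood Nr1d1 (6.45), Serpinb10 (6.60), Reck (6.43) and Tppp3 (6.46) lay at or near the floor and Ahsp (14.07) near the top of the scale, where a fall can show little or not at all. A rise of a probe dim in blood can be compressed as well, so part of some positive differences may be one of scale. All these genes were among the 266 probes that passed. Under other settings some calls ended: C4b (0.0659) and Tppp3 (0.121) without background correction, Mcm6 (0.0866) and Ahsp (0.0751) with no filter on dim probes, and Cd68 (0.0623) and Jchain (0.114) with each tissue normalized on its own. S100a8 did not pass with separate normalization (0.163) or no filter (0.0934), nor Cox5a with these (0.0785 and 0.0704) or without background correction (0.054).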

How the results depend on the processing

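Leaving out 3 blood arrays and using a muscle score as a covariate were alternatives chosen after the data had been seen. No called gene or list named in the report reversed its direction under an alternative, but the balance of some counts did.

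The 1820 lung calls became 170 with median scaling (73.5% higher against 47.1%), all 170 shared with the main count, 158 with a fold of at least 1.5 as well, and 819 at an adjusted p under 0.01. Falls outnumbered rises in the main count (857 higher, 963 lower), while rises outnumbered falls with cyclic loess (895 and 881), with median scaling (125 and 45), with a fold of at least 1.5 (130 and 28) and at an adjusted p under 0.01 (421 and 398). The residual SD under median scaling was 0.124 against 0.073. Apart from the replicate block given below, the other settings gave 1544 (no filter on dim probes) to 2023 (no background correction), with 1665 when the muscle score was a covariate, and the authors' values gave 1983, of which 1783 were shared. Leaving out 1 array gave 1352 to 1970. Of 114 named lung genes past the test, 92 stayed past it in every fit without 1 array, 113 with the authors' values, 109 with cyclic loess and 38 with median scaling.

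The 0 blood calls became 6 without background correction, 7 with the authors' values, 4 with array weights, 5 with a variance trend and robust moderation, and 2 (Lbp and Ubd) without the 3 arrays apart on the first component. The 4 under array weights were LOC313824, Mrps18b, Slpi and Ubd, and the 5 under the variance trend were LOC313824, Ppp1r3b, Serpinb1a, Slpi and Zfp532. Leaving out 1 array gave 0 to 18: 18 without silica replicate 4, 2 without air replicate 4 (Cd3d and Sec14l1), 1 without silica replicate 2 (LOC313824), 1 without silica replicate 6 (Ubd) and 0 in the other 8 fits. The cause was not tested. Serpinb1a, Lbp, Cd3d and Sec14l1 lay outside the rule for naming genes.

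The 21 lung lists became 3 with an estimated correlation, and stayed at 20 to 24 without any 1 array, 20 of the 21 past the test each time. The 6 blood lists became 2 with an estimated correlation, 9 without the 3 arrays apart, and 4 to 8 without any 1 array, 4 of the 6 past the test each time.

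The 266 probes whose effect differed between tissues became 510 with each tissue normalized on its own, 492 with no filter on dim probes (219 higher and 273 lower in lung, against 170 and 96), and 102 with a fold of at least 1.5 as well. Leaving out 1 rat gave 191 to 410, the highest without silica replicate 6. The 681 of 1193 lung calls with the same direction in blood became 58 of 98 with a fold of at least 1.5. They became 46 of 58 at an unadjusted p under 0.01 in blood. Fewer probes enter these counts. The causes of the other changes were not tested.

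Replicate numbers did not pair the samples: deviations of same-numbered air and silica arrays correlated above 0.1 for 2 of 6 numbers in lung and 4 of 6 in blood, and 0 lung and 2 blood air arrays correlated best with their own number. With a replicate block there were 1130 lung calls (87 of the 114 named genes, with Dlk1, Igfbp6, Ctsk, Lgals3, Postn and Mx2 among those lost), 5 blood calls (Cdc5l, Gstm1, LOC500183, Tcn2 and Upp1, outside the naming rule), 23 lung lists, 7 blood lists and 245 probes that differed between tissues. Under that block the difference between tissues did not pass for Ahsp (0.051), Cox5a (0.0679) and S100a8 (0.089), nor the lung macrophage list (0.0735), while the lung neutrophil (0.0452), interferon (0.0453) and oxidative phosphorylation (0.0484) lists and the blood immediate early list (0.0397) passed. A BeadChip block and the authors' values for the difference between tissues were not run.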

Other observations

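The test below was chosen after the fall of Upk3b in lung had been seen. Genes known from mesothelium, the lining of the pleura, were read in lung as values with no explanation. Keratin Krt19 had a log2 fold change of -0.24 ± 0.06 (adjusted p = 0.0258) and Upk3b one of -0.90 ± 0.26 (adjusted p = 0.0368, lost in the fits without single arrays named above). Mesothelin (Msln) had -0.27 ± 0.24 (adjusted p = 0.519), Gpm6a -0.15 ± 0.06 (adjusted p = 0.0904), Aldh1a2 -0.10 ± 0.03 (adjusted p = 0.063), Upk1b -0.07 ± 0.02 (adjusted p = 0.0519) and Calb2 -0.01 ± 0.01 (adjusted p = 0.785). So 2 of 7 passed, both downward, but Upk3b prompted the choice of these genes and its pass adds nothing. Krt19 was abundant (12.57 in air rats), and from which cells its fall came was not tested. Calb2 (6.50 in air rats), Upk1b (6.59), Gpm6a (6.71) and Aldh1a2 (6.75) were dim, so a fall can show little. Over all lung probes tested, 1820 of 11285 passed. The other mesothelial genes chosen were not among the tested probes.

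Several genes outside the lists had higher means after silica in both tissues and were picked here after their values were seen. Chi3l1, the chitinase-like protein, had log2 fold changes of 1.34 in lung and 0.44 in blood, Serpinb1a 0.64 and 0.73, Ptafr 0.76 and 0.49, and the adaptor Myd88 0.26 and 0.57. Lrg1, a leucine-rich glycoprotein of the acute phase, had 0.17 in lung and 0.56 in blood. All 5 passed the adjusted test in lung, and in blood their unadjusted p lay under 0.01 with none past the adjusted threshold.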
